A study of Mus musculus with 1000 samples.

How the data were processed

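Founder C57BL/6NCrl males received 3 doses of ENU at 100 mg/kg, and their third-generation descendants were usually sampled at 8 to 12 weeks of age, per the labels' protocols. The brain without the cerebellum was homogenised, and total RNA was converted to 3' cDNA with the SMART-Seq v4 3' DE kit, from 4 ng of RNA with 8 cycles of amplification. Batches of 1152 samples filled 12 plates, each row of 12 wells was joined into one pool, and the 96 pools of a batch were combined for sequencing. A 3' library reads the ends of transcripts, so it reports transcript abundance and not the sequence of upstream exons.

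The submitters' processing notes name the aligner GSNAP and the genome build GRCm38. The counting method and normalization are not given in the sources used here. The one table analysed here is an index made by the authors, with 3 columns that hold a running row number, a library name and a part name. It was tested column by column, and its only numeric column is the running row number. It has no unit of measurement, and 0 columns of per-sample measurements. The expression data it points to were not analysed here, so depth per sample, replicate spread and differences between groups are not reported.

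Samples were grouped by the genotype and candidate fields of the labels where these were filled, and otherwise by the ENU number in the title. Plate label, plate row, S number and animal number were read from the titles, taking the digits after G3 as the animal number. Each title was matched exactly to a library name of the lookup table. Gene and codon positions were computed from GENCODE release M21, whose build, GRCm38, is the one the processing notes name. Each transcript was walked from its annotated start codon to the labelled residue, and the reference codon was translated. Only coding transcripts of the basic set with complete ends were used. Positions count from 1. No variant was called here, and the labelled changes are the submitters' own.

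The planned count model for m/m against +/+ mice of the Ddhd2 family, the test of Ddhd2 level by genotype and the tests of gene lists could not be run, since they need expression values. The rule for naming genes, fixed before the data were examined, names none without expression values. Ddhd2 and Idua are named only as the labelled loci. Genotype counts were tested with exact binomial and Fisher's exact tests, two-sided, in SciPy 1.17.1 under Python 3.11.15. Intervals are exact Clopper-Pearson intervals at the 95% level.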

Results

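Brain RNA was profiled by 3' RNA sequencing in 1000 mice descended from founders treated with N-ethyl-N-nitrosourea (ENU), a mutagen that introduces point mutations into the germ line. The labels of 26 mice place them in an annotated subset, and the labels of the other 974 give no candidate gene, genotype or phenotype. No expression value was analysed here, because the table analysed lists libraries and holds no counts, normalised expression values or depths. The direction or size of change of any gene, including the disease-associated microglia, interferon and astrocyte genes chosen before the data were examined, is therefore not reported.

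Among the 26 mice of the annotated subset used here, the labels name candidate mutations in a pair of genes. Members of the subset outside the mice used here were not examined. Ddhd2, which encodes an intracellular phospholipase and triglyceride hydrolase, was labelled with the change Y89X in 12 mice of one family. Of these, 9 were recorded as +/+, 1 as m/+ and 2 as m/m. Idua, which encodes the lysosomal enzyme alpha-L-iduronidase, was labelled with the change E130V in 1 m/+ and 1 +/+ mouse of another family. A further 12 mice, all of one other family, were labelled unaffected and had no recorded genotype.

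The phenotype field was filled for 2 of the 12 mice of the Ddhd2 family. One m/m mouse was recorded as DAM and the single m/+ mouse as maybe DAM. The other m/m mouse and the 9 +/+ mice had no recorded phenotype. Heterozygotes made up 8.33% of the family, with an exact Clopper-Pearson 95% confidence interval of 0.211% to 38.5% (n = 12), which covers counting error only.

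Ddhd2 (ENSMUSG00000061313.8) lies on the minus strand of chromosome 8 at 25725346 to 25754596 in GRCm38. In its principal transcript (ENSMUST00000033975.7), codon 89 is TAT and encodes tyrosine in the reference, the residue the label names. The codon occupies positions 25752244 to 25752246 in coding exon sequence, in exon 3 of 18. The protein of this transcript has 699 residues, and the codon lies 3877 bases upstream of the transcript's annotated 3' end. In the alternative transcript ENSMUST00000211688.1, residue 89 lies in exon 1 of 16 and is serine. The label's numbering therefore matches the principal transcript and not the alternative one.

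Idua (ENSMUSG00000033540.18) lies on the plus strand of chromosome 5 at 108660331 to 108684557 in GRCm38. Codon 130 of ENSMUST00000071650.12, a principal transcript with a protein of 643 residues, is GAG and encodes glutamate, the residue named in the label. It occupies positions 108679709 to 108679711 in exon 5 of 15, and lies 2721 bases upstream of the annotated 3' end. ENSMUST00000112563.8 places residue 130 at the same position, in exon 4 of 14. In ENSMUST00000119212.7 residue 130 is also glutamate but lies at 108680149 to 108680151, so the residue alone does not tell these transcripts apart.

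The library titles carried 88 different ENU numbers, which are taken here to name families. Among the libraries used here, 79 of these families had 12 mice, 7 had 6 mice, 1 had 8 mice and 1, the Idua family, had 2 mice. These counts need not be full family sizes, since libraries outside these 1000 were not searched for further members. The titles placed the 1000 libraries in 85 plate rows on 19 plate labels. In the library protocol the 12 wells of a row are joined into one cDNA pool before the final library is made. Among the libraries used here, each of the 88 families lay within a single plate row. Among these libraries, a single family occupied 82 of the rows, and 3 rows held a pair of families with 6 mice each. Some single-family rows, the Idua row among them, held fewer than 12 of these libraries, and their other wells were not examined.

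Genotypes of the Ddhd2 family could thus be compared within one cDNA pool, since all 12 libraries lay in row G of the plate labelled 200Q. Animals 1 to 6, in wells 1 to 6 of that row, were 3 +/+, 1 m/+ and 2 m/m. Animals 19 to 24, in wells 7 to 12, were all +/+. Within the family, genotype is therefore partly mixed with animal number and well position. The 12 unaffected mice lay in row D of the plate labelled 200N, and both Idua libraries in row F of the plate labelled 200C. A comparison of the Ddhd2 family with the unaffected family would cross pools, and the family and the pool cannot be told apart in it.

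All 1000 library titles were found in the lookup table, which lists 23231 libraries under 3 part names. Every one of the 1000 was listed under the part named second. The other 22231 listed libraries were not used here.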

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

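All 1000 titles were also found when case and the read ending were ignored, and when the library description was matched in place of the title. The count of families with 12 mice was 79 over all samples. Restricting this count to samples in the lookup table could not change it, since all 1000 are listed there. The count was 2 when only the annotated subset was used, because its mice used here come from 3 families, of which the Idua family has 2 mice here. The exact binomial test of the heterozygote share in the Ddhd2 family gave p = 0.00635 over all 12 mice. Among the 10 mice that are not m/m, the expected share of heterozygotes is 66.7% if the second parent is m/+, and the exact binomial p against it was 0.000356. A +/+ second parent cannot give the 2 m/m mice, so the 50% expected of its offspring could hold only for part of the family, with several second parents. If all the mice share one heterozygous parent, 50% is the lowest expected share, and it gave p = 0.0215. Both tests assume such a shared parent and were chosen after seeing the data. The alternatives planned for the expression tests were not run: another count model, no filter on low counts, another pseudocount, other controls, an estimated correlation and leaving out each mouse. They need expression values, which were not analysed here. No paired analysis was possible because no expression value was analysed and the replicate numbers follow accession order, so they pair no samples.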

Other observations

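The tests in this part were chosen only after the genotype counts were seen. In the Ddhd2 family, 1 of 12 mice was recorded as m/+, beside 9 +/+ and 2 m/m. If all 12 mice share one parent, that parent must be heterozygous, since both m/m and +/+ offspring occur, and m/+ offspring are then expected at 50% whatever the other parent's genotype. The observed count lay below this share in an exact binomial test (two-sided p = 0.00635, n = 12). This test takes no account of how the family came to be annotated. Without the m/m mice, the exact binomial test against 50% gave p = 0.0215 (n = 10). The animal numbers of the family fall into the blocks 1 to 6 and 19 to 24. All 3 carriers lay in the first block, and the second block held 6 +/+ mice. Fisher's exact test of carriers by block gave a two-sided p = 0.182 (n = 6 against 6), the smallest it can give with 3 carriers, so it decides nothing. A candidate explanation, that the blocks come from different matings with no shared carrier parent, stays open. The labels' growth protocol states that 12 siblings are typically screened, a general statement that is not specific to this family. The first block held 1 m/+ mouse among 6 and the second 0 among 6. The blocks were compared after their genotypes were seen, so no p-value is given for either alone. Entry of +/+ for mice that were not typed was not tested and also stays open. The step of 13 between the blocks is among the widest in the titles: 4 of the 88 families, this one included, have a step of 13 or more. That cut is the family's own step, and smaller gaps occur in many families: 31 of the 88 have a step over 5.

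Within each of the 16 plate labels with more than one plate row, the S number of a library minus the position of its plate row in the alphabet was constant. The other 3 labels hold a single row among the libraries used here and cannot show this. Of the 73 S numbers used, 12 occurred in a pair of plate rows, so an S number alone does not identify a cDNA pool.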
